A study of Mus musculus with 24 samples.

How the data were processed

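5hmC was measured by CMS-IP in splenic B cells of C57BL/6J mice, WT or with Tet2 and Tet3 deleted (DKO), at 0, 24, 48 and 72 h of activation. Per the labels' protocols, genomic DNA was treated with bisulfite, fragments were precipitated with an antiserum against cytosine methylenesulfonate, and libraries were sequenced as paired reads of 50 bp. Spike-ins of lambda DNA and of a puromycin amplicon were not used here. The submitters' processing notes name bcl2fastq 2.20.0.442, BSMAP 2.74, HOMER and edgeR and the builds mm10 and GRCm38, without saying which step each served. How peaks were called and merged is not stated.

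The deposited table held 1 score per peak and library, reads per peak after quantile normalisation across the 24 libraries, inputs included, rounded to whole numbers. The name of the table says that it was quantile normalised. The values show it as well, since all libraries had the same maximum of 10023, medians of 19 or 20 and totals between 13504966 and 13529435. Such values are not counts, so no count model was used and no counting error could be given. The sequencing depth is unknown. Values are relative within a library, and a change of 5hmC over the whole genome cannot be seen. The test for values of this kind had been set down with the other choices, which were made before the data were examined.

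Libraries were grouped by genotype and time from their labels. The WT input at 48 h carries DKO in its genotype entry, while its title, source and library name say WT, and it was kept as WT. The E1 libraries carry a genotype label of their own, WT_B6, and E1 holds no DKO library, so that in a comparison of genotypes E1 and WT overlap in part.

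Peaks were named from a table of genes of GRCm38.p6, matching 635 of the 638 genes asked for in the lists. A peak took the gene whose body held its midpoint (139713 peaks, 58.6%), otherwise the nearest gene end within 100 kb (78921 peaks); 19723 peaks had none. In all 18278 genes had a peak. The table has no strand, so distance is to the nearer gene end rather than to the start of transcription, and the window of 50 kb around Aicda was centred on its lower-coordinate end. A genome sequence was not used here, so the planned search for transcription factor motifs was not run.

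Values were analysed as log2 of the value plus 1 with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups of enriched libraries, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over all 238357 peaks. A peak was called at an adjusted p under 0.05, and every adjusted p of a peak is limma's. There were 12 comparisons: each later time against 0 h within WT and within DKO, DKO against WT at each time, DKO against WT averaged over the times, and the difference between genotypes in the change from 0 to 72 h. Log2 differences between genotypes are DKO minus WT. Standard errors come from the pooled spread of all groups. Values were handled with the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

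Whether the experiment number pairs the libraries was tested before the calls were compared. After removing group means, the 62 pairs of libraries with the same number correlated with r between 0.157 and 0.383 (median 0.282) across peaks, and the 112 pairs with different numbers with r between −0.383 and 0.161 (median −0.194). Removing group means makes the 2 libraries of a DKO group exact opposites and forces values between different numbers down. Those pairs are therefore not separate evidence. The positive values of the same-number pairs show that the numbers pair the libraries. For that reason the fit with the experiment as a block stands beside a result where it changes the call or moves a count by over 1.5 times.

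Gene lists, 19 in all, were among those choices: class switch recombination and somatic hypermutation, B cell identity factors, plasma cell differentiation, LPS and IL-4 activation, bZIP factors, the NF-kB pathway, DNA methylation and TET, B cell receptor and surface, AID off-target loci, cell cycle, markers of T, myeloid, NK, erythroid and megakaryocyte, and stromal and endothelial cells, ribosomal proteins, olfactory and keratin genes, and the immunoglobulin heavy and light chain loci. Each was tested with limma's camera on the mean log2 value per gene, with the preset correlation of 0.01 and with an estimated one, Benjamini-Hochberg adjusted over the lists of a comparison, in 4 comparisons: WT at 72 h, DKO at 72 h, the genotypes over all times and the difference in change. Whether B cells express a marker of another cell type cannot be read from 5hmC.

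Named peaks followed a fixed rule. In those 4 comparisons the 10 higher and 10 lower peaks with the largest log2 change were taken among the called ones, with a mean above the median of all peaks, no overlap between the libraries compared (except for the difference in change), 1 peak per gene and no Gm or Rik gene models; in the other comparisons 3 and 3. Added were every peak within 50 kb of Aicda or in the bodies of Tet1, Tet2 and Tet3, and from each list up to 4 called peaks, 1 per gene, with the lowest p, or the 2 with the lowest p where none was called.

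In the held-out reading, the 500 peaks with the lowest p among those higher in WT at 72 h were chosen in 2 experiments and read in the remaining one. Inputs, which exist for E3 alone, were compared with the E3 library of the same genotype and time, without a test. In the readings of enrichment per experiment, the E1 and E2 libraries were set against these E3 inputs too. Alternatives were the experiment block, E2 and E3 alone, pseudocounts of 0.25 and 4, removal of the lowest quartile of peaks, quantile normalisation of the enriched libraries alone, cyclic loess, no intensity trend, a fit of only the groups compared, each library left out in turn, 100 or 2000 held-out peaks, and for the lists an estimated correlation or peaks in place of gene means. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. An alternative that needed a score per called peak did not apply, as the table gives none.

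The fit was tested on simulated values for WT at 72 h against 0 h with 200 of 238357 peaks changed. The changed peaks were drawn only from those with a mean above the median of all peaks, so recovery at lower peaks was not tested. The fit recovered 14 of 100 peaks changed 2-fold (median estimate 1.03 for a true log2 change of 1) and 62 of 100 changed 4-fold (2.01 for 2). Of its 83 calls, 7 were false. In that setting, without the experiment block, most 2-fold changes were thus missed with 3 libraries per group. The real comparison called 9125 peaks, which makes the adjusted threshold less strict, so these shares need not hold for it.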

Results

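5-hydroxymethylcytosine (5hmC), the first oxidation product that TET dioxygenases make from methylated cytosine, was mapped in splenic B cells of C57BL/6J mice aged 8 to 12 weeks. The method was CMS-IP. Bisulfite turns 5hmC into cytosine methylenesulfonate, and an antiserum against that product enriches the fragments that carry it. Wild-type cells (WT) were compared with cells in which floxed Tet2 and Tet3 had been deleted acutely through CreERT2 (DKO). Cells were unstimulated (0 h) or had been activated for 24, 48 or 72 h with the bacterial lipopolysaccharide LPS at 25 µg/mL and the cytokine IL-4 at 10 ng/mL, which together drive antibody class switching. The title of the series names its question, whether TET enzymes act on expression of the deaminase AID through 5hmC at a superenhancer of its gene, Aicda. There were 12 WT libraries (3 per time), 8 DKO libraries (2 per time) and 4 input libraries made without enrichment (1 for each genotype at 0 and 48 h).

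The values covered 238357 peaks with a median length of 696 bp. They were reads per peak after quantile normalisation, rounded to whole numbers. Library totals therefore lay between 13504966 and 13529435 whatever the sequencing depth, which is unknown. A change is therefore a change relative to the other peaks of the same library, and a gain or loss of 5hmC over the whole genome would leave no trace in it. Replicate numbers mark 3 experiments, E1 to E3, and E1 held WT libraries only. The labels do not say that the libraries of a group came from separate animals. Peaks on chromosome Y had median values of 11 to 25 in the E2 libraries of both genotypes. In E1 and E3 these medians equalled the lowest value of the library. E2 thus came from other animals than E1 and E3. P-values measure only the spread between these libraries, which between E1 and E3 may be technical. Peaks carry the name of the gene whose body holds their midpoint, or otherwise of the nearest gene within 100 kb; exons, introns and promoters were not annotated. Coordinates are those of mm10 (GRCm38).

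The deleted genes were examined first. Peaks in the bodies of Tet1 (18 peaks), Tet2 (21 peaks) and Tet3 (23 peaks) kept their reads in DKO cells. Over all times, the lowest DKO mean was 7.25 at a Tet1 peak, 9.38 at a Tet2 peak and 6.63 at a Tet3 peak, where WT had 10.3, 10.2 and 11.2. One Tet2 peak (chromosome 3, 133480584 to 133481272) was lower in DKO by limma (log2 difference −0.99, adjusted p = 0.0492). Of the 20 fits with 1 library left out, 18 did not keep this call. The labels do not say which exons were deleted, and a 5hmC peak outside the deleted part cannot report on the deletion, so these peaks check nothing.

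At 24 h of activation, WT cells gained 5hmC near Hspe1, which encodes a mitochondrial chaperonin, and near Wfdc15b and Riox2. The peak 15038 bp from Hspe1 (chromosome 1, 55106005 to 55106706) went from 6.0 ± 1.0 to 43.0 ± 8.7 normalised reads (SD, n = 3 at each time). Its log2 change was 2.64 ± 0.39 (SE; limma, adjusted p = 0.00794), beside 2.47 ± 0.42 for Wfdc15b (adjusted p = 0.0386) and 2.39 ± 0.40 for Riox2 (adjusted p = 0.0305). These belonged to 19 peaks called higher and none lower at an adjusted p under 0.05. The early calls were few and fragile. With the experiment as a block 233 peaks were higher and 1 lower, with E2 and E3 alone 2 and 0, with only the groups compared 6 and 0, and with no intensity trend limma called 0 (4931 at an unadjusted p under 0.05). The count was 4 without WT_0h replicate 1 or WT_24h replicate 1, 7 without WT_24h replicate 3, and 11 without WT_0h replicate 2 or replicate 3. The Hspe1 call was lost without WT_0h replicate 1 (adjusted p = 0.0517) or 3 (0.0616) and without WT_24h replicate 1 (0.163) or 2 (0.066). The adjusted p of Wfdc15b reached at most 0.72 and that of Riox2 at most 0.807, both without WT_24h replicate 1.

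By 48 h the gains had spread. The peak 3709 bp from Wfdc15b (chromosome 2, 164210035 to 164211456) had risen by 3.88 ± 0.42 on the log2 scale (limma, adjusted p = 8.38e-06), the peak near Fam98b (chromosome 2, 117228479 to 117231382) by 3.80 ± 0.33 (adjusted p = 2.45e-07) and the peak near BB123696 (chromosome 13, 52708847 to 52710091) by 3.61 ± 0.40 (adjusted p = 9.26e-06). In all 1496 peaks were higher and 10 lower than at 0 h, and the median change of the higher ones was 1.66. Fbp2, Klra6 and Adad1, named among the lower, changed by −1.69, −1.58 and −1.51, and each lost its call in at least 4 of the 6 fits with 1 library left out. With the experiment as a block, 3508 peaks were higher and 353 lower. The count of 1506 fell to 802 without WT_0h replicate 1, to 555 without WT_48h replicate 1 to 679 with no intensity trend and to 167 with E2 and E3 alone.

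At 72 h, 7212 peaks were higher and 1913 lower than at 0 h in WT cells, 9125 peaks in all. The rises were large: 6011 of the higher peaks had changed at least 2-fold, and their median log2 change was 1.70, against −0.86 for the lower peaks. Slc1a3, which encodes a glutamate transporter, had a peak 18371 bp away (chromosome 15, 8614446 to 8617061) that went from 32.0 ± 6.1 to 630.0 ± 27.9 normalised reads (SD, n = 3), a log2 change of 4.27 ± 0.29 (limma, adjusted p = 8.41e-10). The peaks named for Gpr135, an orphan receptor (chromosome 12, 72036674 to 72037905), Wfdc15b, Rnf24, Fam98b, BB123696, Cpeb2, Sh2b2, Ust and Hspe1 rose by between 4.07 and 5.04. Of 10 named lower peaks, 3 kept their calls with each library left out in turn. They lay near Akap7, which encodes an anchoring protein for protein kinase A (chromosome 10, 25123897 to 25124540, −2.15 ± 0.43, adjusted p = 0.00225), in Rasa1, which encodes a Ras GTPase-activating protein (chromosome 13, 85266966 to 85267490, −2.00 ± 0.40, adjusted p = 0.00237), and near the kappa variable segment Igkv8-24 (−1.97 ± 0.42, adjusted p = 0.0046; −1.28 without WT_72h replicate 2). Fhit, Serinc5, Hdac9, Scn2a, Egfl6, Ugp2 and Tmem30c had peaks with log2 changes of −1.89 to −2.15 that did not keep their calls in every such fit. Fhit reached an adjusted p of 0.09 without WT_0h replicate 3, and without WT_72h replicate 2 Serinc5, Hdac9 and Scn2a changed by −1.35, −0.99 and −1.22.

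The 72 h counts depended on how the experiments were handled. With the experiment as a block, 12567 peaks were higher and 10048 lower, so that the share of higher calls went from 79.0% to 55.6%. The block kept all 9125 calls in their direction. With E2 and E3 alone there were 2657 higher and 110 lower peaks. The lower count was the less stable one: it was 457 with only the groups compared, 518 with no intensity trend and 1105 with cyclic loess, where the higher count was 6417, 5296 and 8127. It was 528, 1070 and 1047 without WT_0h replicate 1, 2 or 3, and 943 and 1167 without WT_72h replicate 1 or 2. The higher count was 4889 without WT_0h replicate 1 and 4749 without WT_72h replicate 1.

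**Figure D1:**
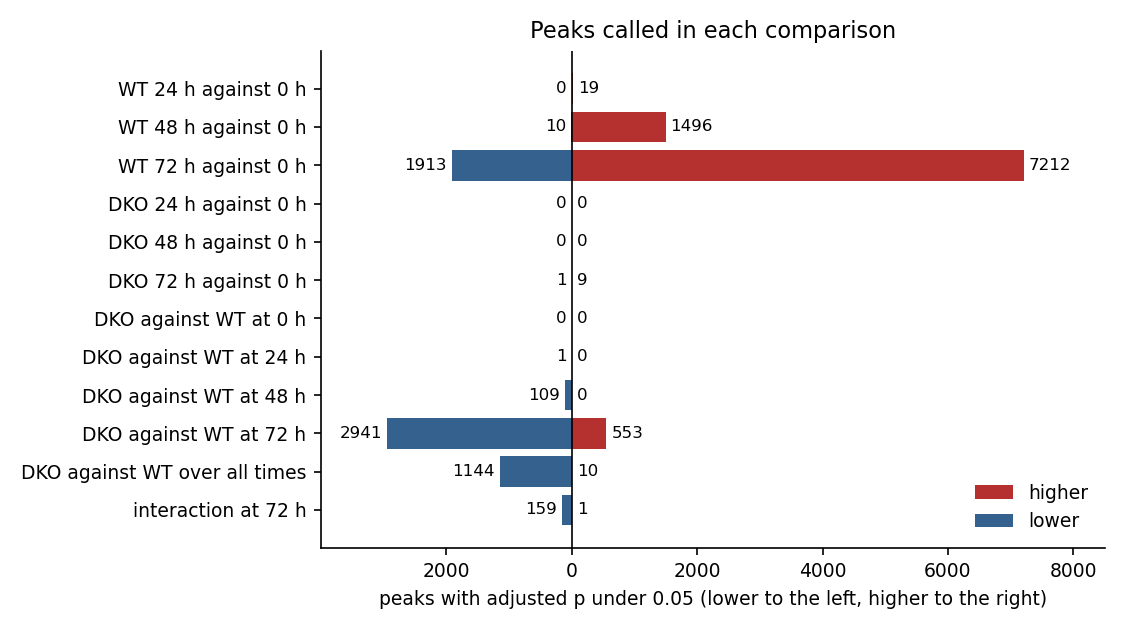
Number of peaks called higher (right) or lower (left) on the x axis in each of the 12 comparisons on the y axis, by limma at an adjusted p under 0.05. WT at 72 h against 0 h has the most calls, 7212 higher and 1913 lower, while DKO at 72 h against 0 h has 9 higher and 1 lower.

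Genes of the LPS and IL-4 response were among those with rising peaks in WT cells. Of 481 peaks of 29 such genes, 74 in 20 genes rose by 72 h and none fell (adjusted over the list alone, 95 rose and 1 fell; at an unadjusted p under 0.05, 126 and 12; with the block 108 and 6). Nfil3, a basic leucine zipper factor needed for switching to IgE, carried a peak in its body (chromosome 13, 52966142 to 52979478) that rose from 168 ± 36.9 to 2267 ± 216 normalised reads (SD, n = 3), a log2 change of 3.77 ± 0.18 (limma, adjusted p = 1.22e-12). Next to Cish, a feedback inhibitor of cytokine signalling (chromosome 9, 107297049 to 107312853), the change was 3.03 ± 0.18 (adjusted p = 3.63e-11), and in Cd86, which encodes a costimulatory ligand (chromosome 16, 36631431 to 36645815), the rise was 2.83-fold (adjusted p = 3.49e-08). Basic leucine zipper (bZIP) factors showed 42 of 299 peaks higher and 1 lower (50 and 3 adjusted over the list alone; 54 and 6 with the block). Besides Nfil3 these included Batf, an AP-1 factor needed for Aicda expression (chromosome 12, 85662816 to 85667593, 21516 bp from the gene, 2.68 ± 0.20, adjusted p = 3.53e-09), its relative Batf3 (2.45 ± 0.30) and Bach2 (0.61 ± 0.05). The set test camera, with its preset correlation of 0.01, placed both lists above the other genes (adjusted p = 7.38e-06 for LPS and IL-4, 5.44e-05 for bZIP). With an estimated correlation, adjusted p = 0.134 for both, and with an estimated correlation and the experiment as a block adjusted p = 0.0422 and 0.0748.

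**Figure D2:**
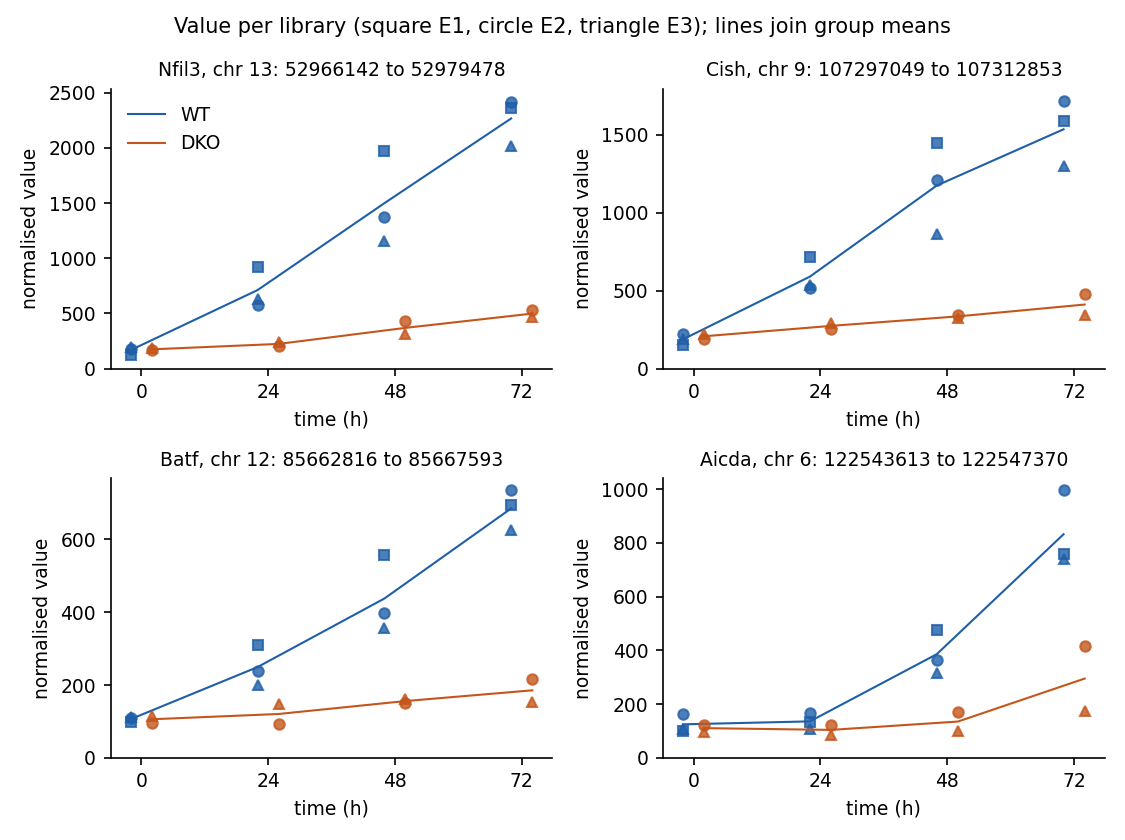
Normalised value (y axis, reads per peak) against hours of activation (x axis) at 4 named peaks, 1 point per library, with lines through the group means; WT points stand slightly left and DKO points slightly right of each time, and squares, circles and triangles mark experiments E1, E2 and E3. At the Nfil3 peak WT rose to 2267 ± 216 (SD, n = 3) at 72 h and DKO to 498.5 ± 41.7 (SD, n = 2).

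Marker genes of T cells also had rising peaks over the same time. Of 309 peaks of T cell markers, 19 rose and 1 fell (22 and 1 adjusted over the list alone; 27 and 8 with the block), among them peaks near Thy1 (2.04 ± 0.23), Cd5 (2.65 ± 0.39), which B cells can also express, Ctla4 (1.10 ± 0.16) and Cd8b1 (2.44 ± 0.39). Camera placed the list above the others (adjusted p = 0.0162; with an estimated correlation, adjusted p = 0.17; 0.0648 with E2 and E3 alone and 0.0775 with peaks in place of gene means). Of the other cell types, myeloid markers had 11 peaks higher and 5 lower of 186 (13 and 5 adjusted over the list alone; camera adjusted p = 0.928), with Csf3r, the G-CSF receptor, at 3.81 ± 0.41 and Itgam at −0.97 ± 0.20. Stromal and endothelial markers had 7 higher and 0 lower of 247 (7 and 0 adjusted over the list alone, 14 and 14 at an unadjusted p under 0.05 by limma; camera 0.688). Erythroid and megakaryocyte markers had 1 higher and 0 lower of 60 (1 and 0 over the list alone, 5 and 7 unadjusted; 0.537). NK cell markers had 0 of 62 in either direction (0 and 0 over the list alone, 3 and 3 unadjusted by limma; 0.529). With the block these 4 lists had more lower calls: myeloid 15 higher and 10 lower, stromal and endothelial 10 and 9, erythroid and megakaryocyte 1 and 3, NK cell 3 and 2.

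Several lists of B cell genes were placed below the other genes. Immunoglobulin light chain peaks fell: 44 of 627, in 37 genes, were lower and 1 was higher (72 and 2 adjusted over the list alone; 136 and 2 with the block), and camera gave an adjusted p of 5.5e-33 (with an estimated correlation, adjusted p = 0.068, and 0.0032 with the block as well). Examples near kappa variable segments on chromosome 6 were Igkv4-81 (68979746 to 68983471, −0.74 ± 0.14), Igkv1-88 (−0.93 ± 0.19), Igkv4-73 (−1.03 ± 0.21) and Igkv5-48 (−1.25 ± 0.26). Camera also placed the heavy chain list below the other genes (adjusted p = 7.38e-06, and 0.000696 with an estimated correlation), although few of its peaks were called. Of 154, 3 were higher and 4 lower (6 and 10 adjusted over the list alone, 8 and 16 with the block). Within it a peak 562 bp from Ighg1, the constant region of IgG1 (chromosome 12, 113329022 to 113333149), rose by 1.41 ± 0.23 (adjusted p = 0.000188). B cell receptor and surface genes had 6 peaks higher and 15 lower of 439 (6 and 20 over the list alone; 11 and 56 with the block; camera down, adjusted p = 0.00328; with an estimated correlation, adjusted p = 0.134, and 0.0081 with the block as well). B cell identity factors had 25 higher and 18 lower of 1014 (27 and 26 over the list alone; camera down, adjusted p = 0.00527; with an estimated correlation, adjusted p = 0.134, and 0.0746 with the block as well), although single peaks in Tcf4 (2.26 ± 0.22) and Lef1 (3.06 ± 0.38) and near Foxp1 (3.03 ± 0.37) rose. With the block the balance of this list turned, to 47 higher and 86 lower.

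For the other lists camera made no call in WT at 72 h. Class switch recombination genes had 21 peaks higher and 2 lower of 297 (21 and 3 adjusted over the list alone; adjusted p = 0.283), which included Apex2 (3.44 ± 0.40) and Msh6 (2.46 ± 0.39), repair genes that act on AID lesions. Plasma cell genes had 20 higher and 6 lower of 487 (22 and 7; 0.537), with peaks near Irf4 (1.43 ± 0.22) and Prdm1 (1.81 ± 0.28), factors of plasma cell differentiation. The NF-kB pathway had 30 higher and 2 lower of 435 (34 and 6; 0.385), for example Nfkb1 at 3.11 ± 0.31 and Tnfaip3 at 1.00 ± 0.10. DNA methylation and TET genes had 11 higher and 1 lower of 342 (11 and 1; 0.537), with a peak 80972 bp from Tet2 at 2.71 ± 0.30 and one in Tdg, a glycosylase that removes oxidised cytosines, at 1.21 ± 0.15. AID off-target loci had 29 higher and 5 lower of 463 (39 and 13; 0.209), for example Mir155hg at 1.95 ± 0.21. Cell cycle genes had 11 higher and 1 lower of 303 (11 and 1; 0.541), for example Cdk1 at 2.75 ± 0.36. Ribosomal protein genes had 12 higher and 1 lower of 111 (14 and 1; 0.394), and olfactory and keratin genes, fixed as a silent control, had 5 higher and 0 lower of 53 (6 and 0; 7 and 3 unadjusted by limma; 0.434). The block moved these counts and made them less one-sided. With it class switch genes had 25 higher and 10 lower, plasma cell genes 40 and 24, the NF-kB pathway 54 and 23, DNA methylation and TET genes 25 and 18, AID off-target loci 49 and 30, cell cycle genes 20 and 14, and ribosomal protein genes 17 and 3. Olfactory and keratin genes had 6 and 0. Over all peaks, 3.03% were higher and 0.803% lower without the block. Ribosomal protein genes, also fixed as a control (10.8% higher), and olfactory and keratin genes (9.43% higher) both lay above that share. For the NF-kB and ribosomal lists the median over genes was at or below 0 (−0.01 for ribosomal) where mean and test pointed up. In the other comparisons the signs differed only for lists that camera did not call.

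**Figure D3:**
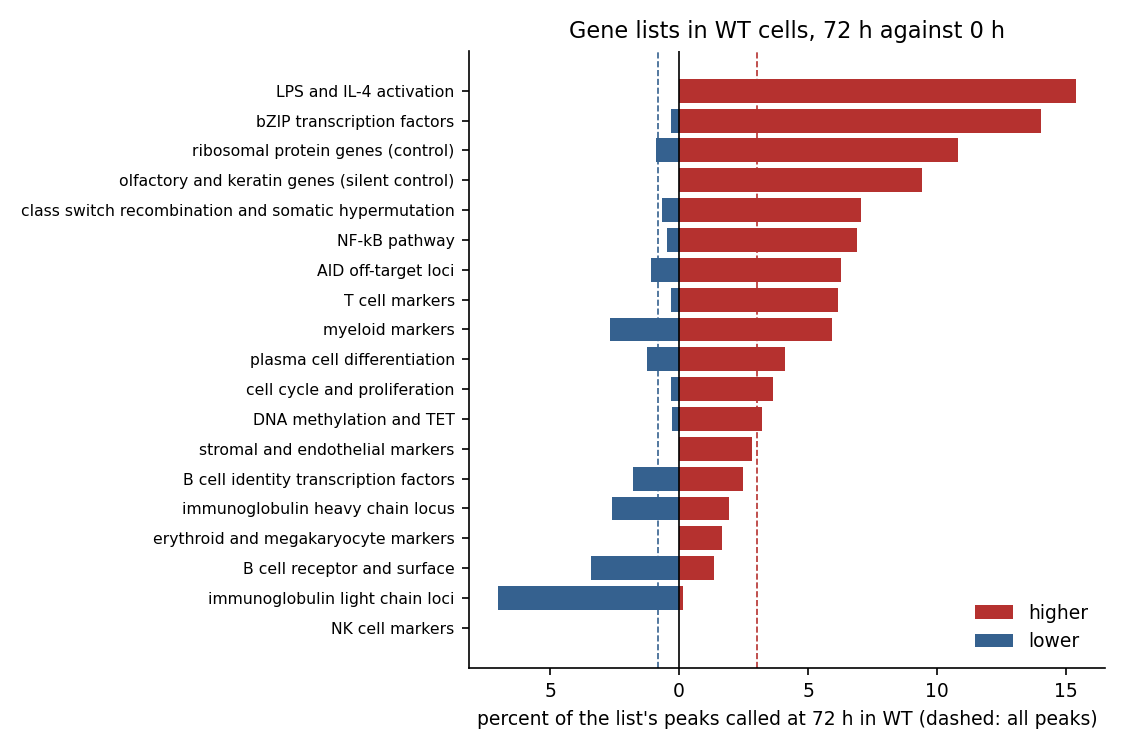
Percent of the peaks of each gene list called higher or lower (x axis, percent) for each list (y axis) in WT at 72 h against 0 h, by limma at an adjusted p under 0.05; dashed lines mark all peaks, 3.03% higher and 0.803% lower. The LPS and IL-4 list has 74 of 481 peaks higher, and the light chain loci have 44 of 627 lower.

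At the Aicda locus, which the series is about, 5hmC rose in WT cells mainly at a peak outside the gene, 8318 bp below its lower end (chromosome 6, 122543613 to 122547370; Aicda lies at 122553809 to 122564180). This peak had 125 ± 34.3, 136 ± 30.7, 386 ± 82.7 and 832 ± 141 normalised reads at 0, 24, 48 and 72 h (SD, n = 3), a log2 change of 1.63 ± 0.26 at 48 h (limma, adjusted p = 0.000847) and 2.75 ± 0.26 at 72 h (adjusted p = 1.01e-07). In DKO cells it had 110.5 ± 19.1, 104.0 ± 26.9, 135 ± 48.1 and 295 ± 170 (SD, n = 2). A second peak, in the neighbouring gene Mfap5 (122527659 to 122530441), followed the same course in WT, with log2 changes of 1.20 ± 0.22 at 48 h (adjusted p = 0.00317) and 2.21 ± 0.22 at 72 h (adjusted p = 1.54e-07). Of the 25 peaks within 50 kb of that end of Aicda, 5 were higher in WT at 72 h and none lower. The remaining ones were a peak over the Aicda body (122552980 to 122561507, 0.45 ± 0.13, adjusted p = 0.0447) and 2 more in Mfap5 (122525581 to 122527309, 2.24 ± 0.64, adjusted p = 0.0423, and 122521821 to 122523605, 1.99 ± 0.39, adjusted p = 0.00212).

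DKO cells had less 5hmC than WT at the first 2 of these Aicda-region peaks. At the peak below Aicda the DKO minus WT log2 difference was −1.53 ± 0.29 at 48 h (limma, adjusted p = 0.0422) and −1.61 ± 0.29 at 72 h (adjusted p = 0.00465), and at the Mfap5 peak it was −1.32 ± 0.24 (adjusted p = 0.0386) and −1.55 ± 0.24 (adjusted p = 0.00158). Within DKO the change of the Aicda peak from 0 to 72 h was 1.29 ± 0.32, with an adjusted p of 0.371, or 2.27e-05 with the experiment as a block, and the difference between the genotypes in that change was −1.46 ± 0.42 (adjusted p = 0.208, blocked 6.28e-05). For the Mfap5 peak that difference was −1.38 ± 0.34 (adjusted p = 0.127, blocked 0.00236). The block also called 4 more region peaks lower in DKO at 72 h, those at 122552980 (Aicda body, adjusted p = 0.0286), 122525581 (0.00989), 122521821 (0.0383) and 122537933 (0.0276). It further called the peak at 122525581 higher in WT at 48 h (0.0154), and the peak at 122537933 higher in WT at 72 h (0.0115) and lower in the difference in change (0.0396). No peak of the region was called between genotypes at 0 or 24 h by limma, and 0 had an unadjusted p under 0.05.

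Several of these calls at Aicda rested on single libraries. The 2 DKO libraries at 72 h differed, 415 in replicate 2 and 175 in replicate 3. Without replicate 3 the genotype difference at the Aicda peak was −0.99 (adjusted p = 0.126) and the DKO change was 1.91 (adjusted p = 0.0185). Without DKO_72h replicate 2 the difference in change was −2.08 (adjusted p = 0.0265). At 48 h the genotype differences of both peaks were lost without DKO_48h replicate 2 or 3 or WT_48h replicate 1 or 2, with adjusted p from 0.143 to 0.475 for Aicda and from 0.065 to 0.469 for Mfap5. The WT change of the Mfap5 peak at 48 h was lost without WT_48h replicate 1 (adjusted p = 0.078). With E2 and E3 alone the Aicda peak had adjusted p of 0.397 in WT at 48 h and 0.0588 between genotypes at 72 h, and with no intensity trend 0.0646 and 0.0727. The peak over the Aicda body lost its WT call with any 1 of the 6 libraries left out (adjusted p from 0.052 to 0.213), and the Mfap5 peak at 122525581 lost its call without WT_0h replicate 1 or 2 or WT_72h replicate 1 or 3 (0.104 to 0.239).

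**Figure D4:**
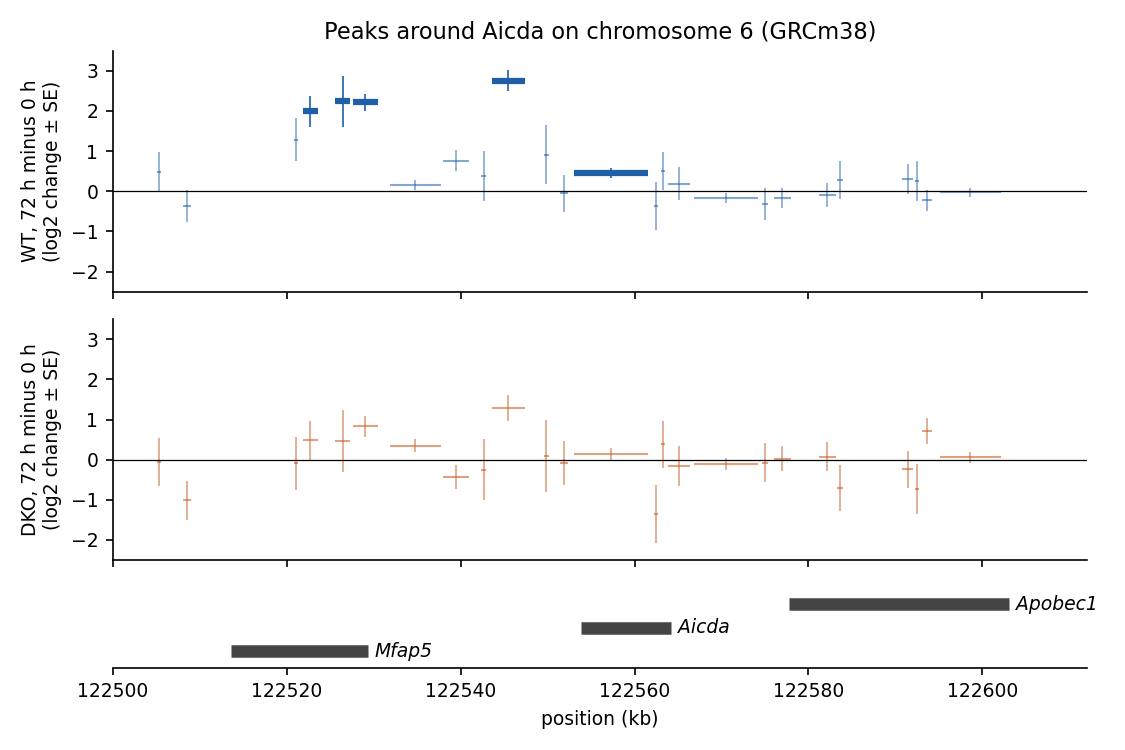
Log2 change (y axis) at the 25 peaks within 50 kb of the lower end of Aicda against position on chromosome 6 (x axis, mm10), with gene bodies drawn to scale; bars are standard errors and thick marks have an adjusted p under 0.05. The peak at 122543613 to 122547370 rose by 2.75 ± 0.26 in WT at 72 h, against 1.29 ± 0.32 in DKO.

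In DKO cells few peaks were called with activation, from 2 libraries per time. At 24 and 48 h limma called 0 peaks in either direction (3323 and 6627 peaks had an unadjusted p under 0.05; with the block 0 and 9 calls). At 72 h 9 peaks were higher and 1 lower (18115 unadjusted). Nfil3 (1.51 ± 0.23, adjusted p = 0.0278), Fam98b (2.84 ± 0.41), Slc1a3 (2.18 ± 0.36), Ccdc18 (2.98 ± 0.47), Morrbid (2.36 ± 0.37), Cnksr3 (1.98 ± 0.32), Kctd1 (1.81 ± 0.30), Ly75 (1.79 ± 0.26) and Auh (1.52 ± 0.23) rose, and Pnkd fell by 2.76. No gene list was called by camera (adjusted p from 0.604), and Nfil3 was the single called gene in the LPS and IL-4 list and in the bZIP list (with the block 5 peaks higher and 1 lower, and 4 and 6). With the block, 717 peaks were higher and 798 lower, with E2 and E3 alone 3 and 0, and with no intensity trend or only the groups compared limma called 0 (19313 and 9108 at an unadjusted p under 0.05). All 10 calls were lost without DKO_0h replicate 2, which left 1 call in all, and without DKO_72h replicate 2, which left 2. Meanwhile 20 peaks were called without DKO_0h replicate 3 and 356 (80 higher, 276 lower) without DKO_72h replicate 3. At 48 h, 14 peaks were lower without DKO_48h replicate 3.

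Before activation no difference between the genotypes passed the test, as limma called 0 peaks at 0 h (3513 at an unadjusted p under 0.05, 1 with the block, 2 without DKO_0h replicate 3). At 24 h the Nfil3 peak was the 1 call, lower in DKO with a log2 difference of −1.64 ± 0.21 (limma, adjusted p = 0.00349), with 224 ± 21.9 normalised reads in DKO (SD, n = 2) against 711 ± 186 in WT (SD, n = 3). With the block 7 peaks were lower. The Nfil3 call was lost without DKO_24h replicate 2 (−1.54, adjusted p = 0.426) and without WT_24h replicate 1 (−1.43, adjusted p = 0.0738), which both left 0 calls by limma. With no intensity trend limma called 0 as well (4653 at an unadjusted p under 0.05). Without DKO_24h replicate 3 there were 3 calls.

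The genotypes parted at 48 and 72 h. At 48 h 109 peaks were lower in DKO and none higher, with a median difference of −1.67. Peaks near Ahr, the aryl hydrocarbon receptor (−2.87 ± 0.53, limma adjusted p = 0.0386), Slc16a12 (−2.73 ± 0.51) and Olig3 (−2.67 ± 0.51) were the lowest. Each was lost in 4 of the fits with 1 library left out. At 72 h 2941 peaks were lower and 553 higher in DKO. A peak in Pla2r1, a phospholipase receptor gene (chromosome 2, 60479642 to 60480441), had 14.0 ± 17.0 normalised reads in DKO (SD, n = 2) and 117 ± 23.2 in WT (SD, n = 3), a difference of −3.69 ± 0.58 (adjusted p = 0.00155; −2.10 and 0.0467 without DKO_72h replicate 2). A peak in Tctn2, a cilium gene (chromosome 5, 124621224 to 124622015), differed by −3.08 ± 0.43 (adjusted p = 0.00051). Near the kinase gene Tyk2 the difference was −3.42 ± 0.57 (adjusted p = 0.00231; −1.99 and 0.0759 without DKO_72h replicate 3). Slc44a5 (2.85 ± 0.58), Zfp600 (2.44 ± 0.53) and Klhl24 (2.23 ± 0.43) were the highest, each lost without at least 1 library. With the block, 996 peaks were lower and 35 higher at 48 h, and 8387 lower and 5254 higher at 72 h. This took the share of higher calls at 72 h from 15.8% to 38.5%. The 48 h count was 7 without DKO_48h replicate 2, 262 without replicate 3, 2 without WT_48h replicate 1 and 11 without replicate 2. It was 53 with only the groups compared, 2 with E2 and E3 alone and 0 with no intensity trend (14835 unadjusted by limma). At 72 h there were 6 higher and 1258 lower with only the groups compared, 10 and 321 with E2 and E3 alone, and 162 and 1088 with no intensity trend. There were 172 and 2471 without DKO_72h replicate 2 and 161 and 1862 without replicate 3. Without WT_72h replicate 1, 2 or 3 there were 115 and 1077, 196 and 1502, and 1192 and 2723.

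Averaged over the 4 times, DKO cells were lower than WT at 1144 peaks and higher at 10. Among the lower ones were peaks of the activation genes Nfil3 (−1.44 ± 0.10, limma adjusted p = 1.68e-08), Cish (−1.16 ± 0.10, adjusted p = 4.64e-07), Batf (−1.11 ± 0.11, adjusted p = 1.13e-05), Mir155hg (−0.92 ± 0.12, adjusted p = 0.000486) and Cd86 (−0.53 ± 0.07, adjusted p = 0.00065). The B cell factors Foxp1 (−1.37 ± 0.21), Tcf4 (−0.92 ± 0.12) and Bach2 (−0.20 ± 0.03), Tdg (−0.50 ± 0.08), the 2 Aicda-region peaks described above (−0.92 ± 0.15 and −0.81 ± 0.12) and the peak near Krt24, a keratin gene (chromosome 11, 99288846 to 99289663, −1.87 ± 0.21, adjusted p = 5.54e-05), were lower as well. Epc1, Clhc1, Lekr1, Mob1b, Car5b, Adamts12, Tiparp, Rpp40 and Aco1 had peaks with log2 differences of −1.11 to −1.49. Ankrd35, the named peak that was higher (0.89 ± 0.21, adjusted p = 0.0484), and Apex2 (−0.97 ± 0.23, adjusted p = 0.0438) lost their calls with the block (0.0661 and 0.0876). The block called 1980 peaks lower and 167 higher. With the 72 h libraries left out, 4 peaks were called, among them Nfil3 (−1.19), Cish (−0.90) and Krt24 (−1.76). In that smaller fit Batf (−0.84, adjusted p = 0.0664), Cd86 (−0.33, 0.811) and the Aicda peak (−0.69, 0.37) kept their sign but not their calls. Single libraries mattered too. The count of 1154 was 599 without DKO_0h replicate 2, 564 without DKO_24h replicate 2 and 757 without DKO_48h replicate 2. It was 615, 588 and 714 without replicate 1 of WT_24h, WT_48h and WT_72h, 202 with no intensity trend and 51 with E2 and E3 alone. The 10 higher calls became 1 to 28 with 1 library left out.

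Among the lists, those of activation had the lowest camera adjusted p over all times. The LPS and IL-4 list had 25 of 481 peaks, in 11 genes, lower in DKO and 0 higher (56 and 1 adjusted over the list alone; 96 and 10 unadjusted by limma; 41 and 0 with the block), with a camera adjusted p of 1.45e-08. The bZIP list had 19 of 299, in 7 genes, lower and 0 higher (25 and 1 over the list alone; 50 and 6 unadjusted by limma), with an adjusted p of 2.79e-07. With an estimated correlation, adjusted p = 0.0893 for both, and 0.0379 for both with the block as well. Ribosomal protein genes, fixed as a control list, were also placed lower by camera (adjusted p = 0.00402, 0.0998 with an estimated correlation, and 0.203 with the block as well). They had 2 peaks lower (7 over the list alone, 4 with the block). A camera call at the preset correlation therefore does not by itself set a list apart. Light chain peaks were placed higher in DKO (adjusted p = 0.00018; with an estimated correlation, adjusted p = 0.551) with 0 of 627 called (0 over the list alone, 35 higher and 5 lower unadjusted by limma). The block added B cell receptor and surface genes (0.116 without it, 0.000739 with it, upwards) and the heavy chain locus (0.071 and 0.0173, upwards, with 2 of its peaks called lower). Of the other cell types, T cell markers had 2 peaks lower and 0 higher (5 and 0 with the block; adjusted p = 0.244).

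The change from 0 to 72 h itself differed between genotypes at 160 peaks, and at 159 of them the change was lower in DKO. The peak in Sf3a1, a splicing factor gene (chromosome 11, 4163896 to 4165191), went from 24.0 ± 2.6 to 163 ± 25.7 normalised reads in WT (SD, n = 3) and from 41.5 ± 7.8 to 22.5 ± 4.9 in DKO (SD, n = 2), with a difference of −3.57 ± 0.46 (limma, adjusted p = 0.0028). Nfil3 differed by −2.26 ± 0.29 (adjusted p = 0.0028), Cish by −2.06 ± 0.28 (adjusted p = 0.00442), Batf by −1.89 ± 0.32 (adjusted p = 0.0193) and Cd86 by −1.22 ± 0.21 (adjusted p = 0.0197). Of the 22 peaks named for this comparison, those in Sf3a1 and Nfil3 kept their calls with each library left out. With no intensity trend neither was called (adjusted p = 0.114 and 0.188), as limma then called 0 peaks in all (20429 at an unadjusted p under 0.05), and with E2 and E3 alone Nfil3 was (adjusted p = 0.018) and Sf3a1 was not (0.15). Cish lost its call without DKO_0h replicate 3 (−1.96, adjusted p = 0.0943). The other 19 lost theirs in 4 to 8 of the 10 fits. The LPS and IL-4 list had 7 of 481 peaks lower, in 6 genes, and 0 higher (27 and 0 adjusted over the list alone; 82 and 4 unadjusted by limma; 43 and 0 with the block; camera adjusted p = 6.47e-05; with an estimated correlation, adjusted p = 0.148, and 0.0651 with the block as well). The bZIP list had 4 lower and 0 higher of 299 (15 and 0; 50 and 1; 25 and 1 with the block; camera adjusted p = 5.33e-07; with an estimated correlation, adjusted p = 0.131, and 0.0573 with the block as well). The heavy chain locus (0.000592; with an estimated correlation, adjusted p = 0.00649, and 0.0153 with the block as well; 0.516 with peaks in place of gene means) and the light chain loci (5.49e-20; with an estimated correlation, adjusted p = 0.131, and 0.0153 with the block as well) were placed upwards in DKO, with 0 peaks called in either by limma (7 higher and 7 lower, and 73 higher and 1 lower, unadjusted). The block called 3 heavy chain peaks lower and 28 light chain peaks higher. With the block 3556 peaks were lower and 1675 higher, a share of higher calls of 32.0% against 0.6%. The count was 4 without DKO_0h replicate 2, WT_0h replicate 1 or WT_72h replicate 1, and 3 without DKO_0h replicate 3. It was 620 and 30 without DKO_72h replicate 2 and 3, 73 without WT_0h replicate 3, 41 without WT_72h replicate 2, 6 with only the groups compared, and 1 with E2 and E3 alone.

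Because these comparisons share libraries, the course was also read in libraries that had not chosen the peaks. When the 500 peaks with the lowest p among those higher in WT at 72 h were chosen in E1 and E2 and read in E3, their median log2 change in WT was 0.43, 1.24 and 2.31 at 24, 48 and 72 h, against 0.04, 0.23 and 0.53 in DKO. Chosen in E1 and E3 and read in E2, it was 0.47, 1.58 and 2.59 in WT and 0.12, 0.61 and 1.27 in DKO. The median DKO minus WT difference was 0.07 in E3 and 0 in E2 at 0 h, and −1.65 and −1.29 at 72 h. At 72 h 100% of the chosen peaks were higher than at 0 h in WT in both readings, and 87% (E3) and 98% (E2) in DKO. Over all peaks the median WT change at 72 h was −0.02 in E3 and −0.04 in E2, and in DKO 0 in both. These are single libraries per genotype and time, so no test was made.

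**Figure D5:**
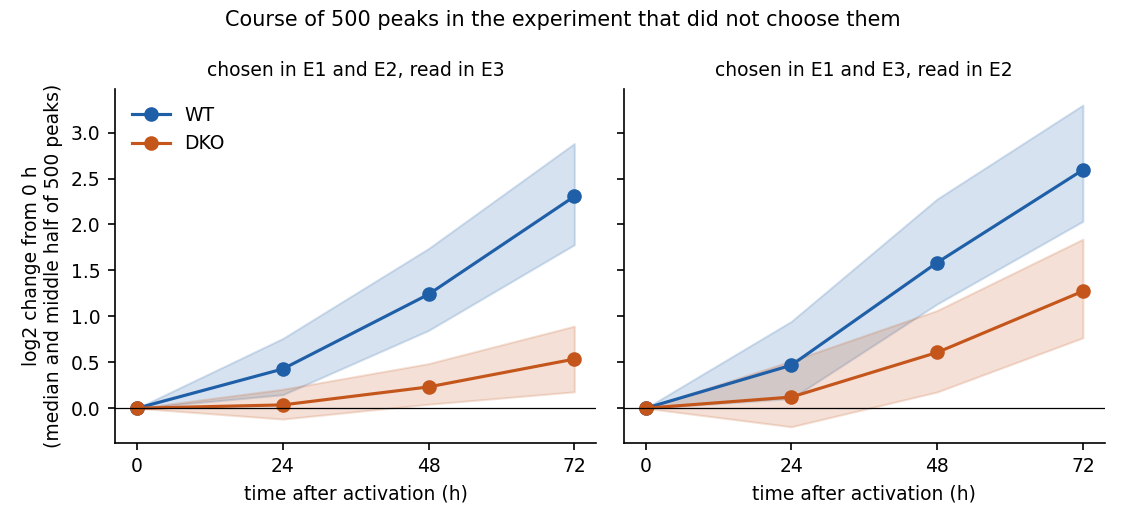
Median log2 change from 0 h (y axis) against hours of activation (x axis) of 500 peaks chosen in other experiments, for WT and DKO, read in E3 and in E2; bands span the 25th to 75th percentile of the peaks. At 72 h WT reached 2.31 (E3) and 2.59 (E2) and DKO 0.53 and 1.27.

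Between each E3 library and the input of its genotype and time, the median log2 difference over all peaks was 0 in all 4 pairs, 14.2% to 15.5% of peaks were at least 2-fold above the input, and 13.2% to 15.1% at least 2-fold below it. Across peaks, which are not independent replicates, the log2 values of library and input correlated with r between 0.815 and 0.835. The inputs had passed through the same quantile normalisation as the enriched libraries, which forces their medians together. There was 1 input per pair, so no test was made.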

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

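Tests of DNA copy number in the rising peaks and the tests of the light chain loci were set down before their results were seen. Chosen only after the results were seen were the tests of stronger and weaker enrichment, of the DKO_72h replicate 3 library, of the E1 libraries, of a linked region, and the counts of other splits of the samples.

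The change from 0 to 72 h differed between genotypes at 160 peaks, tested as a difference of differences. Pdxdc1 alone was higher in DKO (1.15). Lower were F2rl1 (−4.09), Sptssa (−3.64), Sf3a1 (−3.57), Zc3h12c (−3.43), Inf2 (−3.42), Itgb5 (−3.39), Prss42 (−3.35), Rps27l (−3.19), Dkk3 (−3.18), Nek6 (−3.15), Map3k14 (−2.29), Nfil3 (−2.26), Cish (−2.06), Rpl3 (−2), Batf (−1.89), Zbtb46 (−1.62), Cd86 (−1.22), Ccr7 (−0.97), Il4ra (−0.81), Bach2 (−0.49) and Cd83 (−0.43), in log2 units. Of these 22 calls, Sf3a1 and Nfil3 alone were kept with each library left out, and with no intensity trend none was (adjusted p = 0.114 for Sf3a1 and 0.188 for Nfil3). Of the others, 19 were lost without DKO_0h replicate 2 or WT_0h replicate 1, 20 without DKO_0h replicate 3, 18 without WT_72h replicate 1, 16 without DKO_72h replicate 3, 14 without WT_72h replicate 2, 9 without WT_0h replicate 3, 3 without WT_0h replicate 2 or WT_72h replicate 3, and 2 without DKO_72h replicate 2. The lists of LPS and IL-4 activation (camera adjusted p = 6.47e-05), bZIP factors (5.33e-07), the heavy chain locus (0.000592) and the light chain loci (5.49e-20) differed as well; with an estimated correlation the adjusted p was 0.148, 0.131, 0.00649 and 0.131, and with the block as well 0.0651, 0.0573, 0.0153 and 0.0153. With peaks in place of gene means the heavy chain list was not called (adjusted p = 0.516).

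The gains in WT at Nfil3, Cish, Batf and the other rising peaks could come from DNA copy number or from how strongly libraries were enriched. Against copy number, the ratio of the median input change to the median enriched change at the peaks higher at 48 h was 0.0982 (bootstrap SD over peaks 0.0165, and 0.106 at peaks chosen without E3). From 0 to 48 h, the peaks higher at 72 h had median changes of 0.12 in input and 0.68 in the E3 library. There was 1 input per time and none at 72 h. The WT input at 48 h is the library whose genotype entry conflicts, so the argument is limited. Peaks were then chosen without an experiment and read in it, all against the E3 inputs. The median of those higher at 72 h lay below input in WT at 0 h (−0.68, −0.42 and −0.53 in E1 to E3), against stronger enrichment. The median of those higher at 48 h then stood above input (0.97, 0.35 and 0.37), against weaker enrichment for the set. At 48 h in E3, Batf stood above its input (358 against 319). Nfil3 (1153 against 1203) and Cish (865 against 945) did not, although their E1 and E2 libraries exceeded the same E3 input. At 72 h in E1 to E3, Nfil3 had 2362, 2419 and 2019 in WT, and its highest input of either time and genotype was 1203. Cish had 1591, 1716 and 1300, with a highest input of 1134. These values argue against weaker enrichment at the Nfil3 and Cish peaks, although no input was made at 72 h. Weaker enrichment stays open for the falling peaks, since enriched peaks at large fell by up to 0.391 as much. For 24, 48 and 72 h, 1 of 10 splits, the real one, gave 19, 1506 and 9125 calls, against 0 for the highest other split, also among the 4 splits that part all pairs, and 10 splits are too few for a share under 0.05. A gain of 5hmC with activation stays open as a hypothesis, as does a changed mix of B cell subsets or other cells, which was examined only through marker lists.

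The lower 5hmC in DKO at 72 h, at the Aicda region, Pla2r1 and Tctn2 among others, could rest on single libraries or on strain. DKO_72h replicate 3 resembled the mean input most (r = 0.896 across peaks). The inputs are all from E3, however, and every E3 library had an r of at least 0.878, against at most 0.866 in E1 and E2. The held-out difference in E2, which does not use DKO_72h replicate 3, was 0.783 of that in E3. Against the E1 libraries, which are WT only, peaks chosen as lower without E2 or without E3 differed by −0.81 and −1.09 in the experiment left out (all peaks 0). Each choice rested on 1 DKO library per time, and the set chosen without E3 was much the smaller. Chromosomes 3 and 6, which carry Tet2 and Tet3 in turn, held 10.0% of the lower peaks and 10.6% of all peaks. The lower peaks at large were thus not crowded there. A share over whole chromosomes cannot show a shorter linked region from another strain around Tet2 or Tet3. The Aicda region lies on chromosome 6 with Tet3, so linkage stays open for it. Over all times, as 72 h alone was not tested by splits, 1 of 100 splits, the real one, gave as many calls (1154, highest other 47). With E1 kept as WT and genotypes swapped within E2 and E3 it was 2 of 100. These were the real one and the one with both 0 h pairs swapped (1345). Such splits could exclude chance only if the times of an experiment were independent. Libraries of the same experiment number correlated, however (median r = 0.282 across peaks), so chance stays open. If the times share an animal there are 4 arrangements (highest other 0), too few for a share under 0.05. A lower TET activity at these peaks may be the reason, as a hypothesis, while fewer or more slowly activated DKO cells were not tested.

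The fall of the light chain peaks in WT, as at Igkv4-81, was also seen in the unenriched input at 48 h. From 0 to 48 h in E3, the ratio of the median input change to the median enriched change was 0.771 (bootstrap SD over peaks 0.0967, with −0.28 in input and −0.37 enriched). The DKO input changed by a median of 0. Single peaks varied: at Igkv4-81 the WT input went from 266 to 139 and the DKO input from 179 to 139, and at Igkv4-73 the WT input went from 157 to 156. A change in DNA copy or coverage at the loci, such as another mix of rearranged cells, may therefore account for much of the fall up to 48 h. The median fall at 72 h was larger (−0.66), and no input was made at 72 h. There is 1 input per time, and the WT input at 48 h is the library whose genotype entry conflicts. A lower background in activated libraries is argued against, since the difference between light chain peaks and 6270 matched peaks was −0.50. Reads shared between similar variable segments were not tested.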

How the results depend on the processing

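Added after the data were seen were the fits of E1 and E3 alone, with likeness to input as a covariate, with X and Y removed, with 72 h left out, and the block with an estimated correlation. Quantile normalisation limits all results to relative change. Leave-one-out and the alternatives were run for peaks that were called and for Aicda-region peaks called in WT at 72 h, 208 values; other uncalled peaks were not re-run. The motif search and its alternatives (window, GC strata, block, distance) were not run for lack of a genome, and the peak-score alternative had no score to use. Where a fit drops libraries, the spread is estimated from fewer of them; for the rest the cause was not tested.

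Counts of called peaks are given in the order WT 24, 48 and 72 h, DKO 48 and 72 h, then DKO against WT at 0, 24, 48 and 72 h, over all times, and the difference in change. With the replicate block they were 234, 3861, 22615, 9, 1515, 1, 7, 1031, 13641, 2147 and 5231. With E2 and E3 libraries only, WT gave 2, 167 and 2767, DKO at 72 h 3, the genotypes 2 at 48 h, 331 at 72 h and 51 over all times, and the difference in change 1. With no intensity trend, WT gave 0 at 24 h (4931 at an unadjusted p under 0.05 by limma), 679 and 5814, DKO at 72 h 0 (19313 unadjusted), the genotypes 0 at 24 h (4653) and 48 h (14835), 1250 at 72 h and 202 over all times, and the difference in change 0 (20429). With only the groups compared, WT at 24 h gave 6, DKO at 72 h 0 (9108 unadjusted by limma), the genotypes 2, 53 and 1264 at 24, 48 and 72 h, and the difference in change 6. With E1 and E3 libraries only, WT at 24 h gave 51, DKO at 72 h 5, the genotypes 0 at 24 h (3228 unadjusted by limma) and 6362 at 72 h, and the difference in change 968. With likeness to input as a covariate, WT gave 176, 3312 and 19309, DKO 3 and 782, the genotypes 8, 1220 and 13901 at 24, 48 and 72 h and 4631 over all times, and the difference in change 3103. With 72 h left out, the genotypes over all times gave 4.

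With 1 library left out, calls ranged from 4 to 13, 555 to 1460 and 5417 to 8838 in WT; 0 to 0, 0 to 14 and 1 to 356 in DKO; 0 to 2, 0 to 3, 2 to 262 and 1192 to 3915 between genotypes at 0, 24, 48 and 72 h; 564 to 1280 over all times; and 3 to 620 for the difference in change. Both pseudocounts, removal of the lowest quartile, quantile normalisation of the enriched libraries alone, cyclic loess and removal of X and Y kept every total within 1.5 times. By direction, cyclic loess took the lower count in WT at 72 h from 1913 to 1105, a pseudocount of 4 took the higher count over all times from 10 to 19, and a pseudocount of 4, cyclic loess or removal of X and Y took that of the difference in change from 1 to 2.

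Of the 208 named values, the block kept 199 on their side of the threshold and in direction, ended 2 (Ankrd35, Apex2) and added 7, and it changed no other call among these 208. E2 and E3 alone kept 101, no intensity trend 124, only the groups compared 159, E1 and E3 alone 164, removal of the lowest quartile 202, cyclic loess 205, a pseudocount of 4 207, and a pseudocount of 0.25 ended 7. Leave-one-out kept 1541 of 1953. Directions turned 5 times, all at peaks never called in those fits: at Mfap5 (122521821) to −0.13 in WT at 48 h with E2 and E3 alone and to −0.0444 in DKO at 72 h with E1 and E3 alone, and in DKO at 72 h at Mfap5 (122525581) to −0.40 without DKO_0h replicate 2 and −0.60 without DKO_72h replicate 3, and over the Aicda body (122552980) to −0.0190 without DKO_0h replicate 2 (highest 0.28, without DKO_0h replicate 3).

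Of 76 list tests 15 passed, 2 with an estimated correlation, 17 with the block (B cell receptor and surface genes and the heavy chain locus over all times were added), 16 with E2 and E3 alone, 16 with cyclic loess, 18 with peaks in place of gene means and 10 with the block and an estimated correlation. The held-out WT change at 72 h, 2.45 over both readings, was 2.84 with 100 peaks and 1.98 with 2000; both lie as the choice of fewer or more peaks would place them. Without the lowest quartile of peaks, the median difference from input was 0.135 (WT 0 h), 0.0671 (WT 48 h), 0.12 (DKO 0 h) and 0.0709 (DKO 48 h) in place of 0.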

Other observations

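The descriptions here were chosen after the results were seen. In WT at 72 h some genes gained 5hmC at many of their peaks. Batf had 10 of 11 peaks higher, Nfil3 10 of 21, BB123696 18 of 31, Morrbid, a long noncoding RNA gene, 28 of 69, its neighbour Bcl2l11, which encodes a proapoptotic protein, 9 of 31, Auh 17 of 38, Mir155hg 9 of 24 and Nfkb1 10 of 33. The named peaks of BB123696, Auh and Nfil3 lie close together on chromosome 13, between 52708847 and 52979478. Their gains need not be separate. Atxn1 had 23 of 146, Rad51b 17 of 187, Etv6 11 of 109, Zbtb20 11 of 158 and Pvt1 9 of 104. Among the genes with the most falling peaks, Antxr2 had 7 of 80, Pde7a 7 of 54, Cecr2 6 of 43, Nedd4l 6 of 134 and Ebf1, a B cell factor gene, 4 of 95.

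The rising peaks of WT at 72 h had a median length of 1299 bp, and 55.3% of them lay in gene bodies. In DKO at 0 h, a group outside the comparison that chose them, their median value was 29.5. The falling peaks were longer (2194 bp) and higher in DKO at 0 h (135), with 48.4% in gene bodies. The 2941 peaks lower in DKO at 72 h had a median length of 1497 bp, a DKO value of 38.5 at 0 h and 59.8% in gene bodies; over all peaks these were 696 bp, 19.5 and 58.6%.

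The 625 peaks on chromosome Y had median values of 11 to 25 in the E2 libraries, 2 to 3 in E1 and 0 in E3 and the inputs. In E1, E3 and the inputs this median equalled the lowest value of the library, so E2 alone had a median on Y above that. X peaks had medians of 12 to 15 in E2 and 16 to 22 in the others. The experiments thus differed on the sex chromosomes within both genotypes, and E2 came from other animals than E1 and E3. Since E1 held WT libraries only, libraries with signal on Y made up a smaller share of WT than of DKO. Among WT libraries, WT_72h replicate 2 had the highest residual SD (0.599). Groups of 2 libraries shrink residuals more than groups of 3, so residual SDs of DKO and WT cannot be ranked together. Of all enriched libraries, WT_72h replicate 2 had the lowest correlation with the mean input (r = 0.783 across peaks) and DKO_72h replicate 3 the highest (r = 0.896). All inputs are from E3, and this correlation followed the experiment: at least 0.878 in E3, at most 0.866 in E1 and at most 0.822 in E2.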
